A study of Mus musculus with 15 samples.

How the data were processed

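The samples were 15 pieces of mouse lung isolated by laser capture microdissection, in which cells are cut out of a frozen tissue section under the microscope. The mice carried a K-RasG12V knock-in allele, and the lungs were taken 3 months after infection with an adenovirus that delivers Cre recombinase, per the labels' protocols. Normal cells (8 samples) and early hyperplastic lesions (7 samples of about 500 cells each) came from the same lung sections, per the series' design text. The source names split the lesions into H1 (3 samples) and H2 (4 samples). How a lesion was assigned to H1 or H2, how many animals were used and which samples shared an animal are not given in the sources used here. If H1 and H2 were assigned from these same profiles, the comparison between them is not independent evidence that the subtypes exist. Captured regions of the same animal are not independent. P-values over regions measure the spread between these samples, and may be too small (sharing within a group) or too large (sharing between groups).

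RNA was extracted with the PicoPure kit and amplified and labelled with the WT-Ovation One-Direct system, per the labels' protocols, and hybridised to Affymetrix arrays, per the series' design text. The deposited values are log2 signals per probe set. The submitters' processing notes name the affy package and RMA, the method of background correction, quantile normalization and probe summary for such arrays, with no version. The table held 45101 probe sets, of which 64 were array controls and were left out. On every array the values lay on a log scale, and the array medians lay between 3.87 and 4.06. RMA equalises probe intensities, not probe set summaries, so arrays can still differ in the spread of their values. That spread was measured as the standard deviation of the log2 values over the genes of each array. For arrays, the number of samples limits the precision, and values near the background say little about low transcripts.

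Gene names came from the platform annotation paired with the value table. Of the probe sets, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none there. Gene IDs of 34741 probe sets were found in the mouse reference gene table (GRCm38.p6, used for names only), and 0 symbols changed. Probe sets with several symbols or none were not used for gene results. Where a gene had more than 1 probe set, the probe set with the highest mean over all arrays stood for it, which left 18193 genes. For genes named as called, and for Ddr1, probe sets that moved the other way are given with the same comparison.

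Differences were tested with limma (version 3.58.1, R version 4.3.3), using lmFit and eBayes on the deposited log2 values. Lesions were compared with normal cells in a fit with 2 groups. H1 against normal, H2 against normal and H1 against H2 were contrasts in a fit with 3 groups, which shared 1 estimate of the spread over all 15 arrays. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Differences are on the log2 scale with the standard error (SE) of the fit, and group levels are means ± SD.

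Before the data were examined, 31 gene lists were fixed for cell types that the captured tissue could hold and for programs of K-Ras-driven lung lesions. Of their 460 genes, 426 were measured, and 7 genes stood in more than 1 list. A further list, of sex-linked genes, was fixed as a check only and was not tested. Lists were tested with camera, which compares the genes of a list with all other genes, at its preset correlation between genes of 0.01, and adjusted over the lists of a comparison. The same test with the correlation estimated for each list, and fry, which asks whether a list's genes move without comparing them with other genes, were run beside it. The naming of genes was also fixed then. For lesions against normal, up to 12 genes with the largest difference in each direction were to be named, among called genes whose group values did not overlap. The same rule took up to 6 in each direction for H1 and H2 against normal and up to 10 for H1 against H2. Predicted genes, immunoglobulin segments and sex-linked genes were not named by size. Up to 4 members with the lowest p were to be named from a list, and Ddr1 was to be reported in every comparison. A further item that the rule named is not reported here.

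The alternatives were centring of each array on its median, repeated quantile normalization, a filter on dim genes, the mean or the most variable of a gene's probe sets, a trended robust prior, array weights, the replicate number as a block, fits on only the arrays compared, the mean of H1 and H2 against normal in the fit with 3 groups, and leaving out each array in turn. Array spread as a covariate, the difference of the 3′ and 5′ control probe sets of Actb or of Gapdh as a covariate (genes only, not lists), and the removal of the 2 normal arrays with the narrowest spread were added after the data were seen. The main fits, and camera at its preset correlation, were tested on simulated data, and the alternatives were not. Each gene was drawn on its own from its real mean and spread, so without the correlation between genes that real arrays have. The spread was that of the fit with 3 groups. It leaves out differences between H1 and H2, so the shares for lesions against normal may be too high. With 200 changed genes among 18193, a 4-fold change was called in 89.9% of cases for lesions against normal, 80.6% for H1 against normal, 83.8% for H2 against normal and 75.3% for H1 against H2. For a 2-fold change the shares were 49.3%, 15.9%, 27.6% and 4.6% in the same order. For lesions against normal, a simulated list shifted by 1 on the log2 scale was found in 20 of 20 runs, and 0 of 600 unshifted lists were called.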

Results

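Expression was measured on 15 Affymetrix arrays of microdissected lung cells from K-RasG12V mice, which carry an oncogenic K-Ras allele and had been given Cre through an adenovirus. The allele also expresses a colour marker that identifies the cells carrying it. Normal cells gave 8 arrays and early hyperplastic lesions gave 7, of which 3 were labelled H1 and 4 H2. The number of arrays limits the precision of every value. All values are log2 signals, and ± after a difference is its SE.

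The arrays differed in the spread of their values. The standard deviation of gene values within an array averaged 1.38 ± 0.18 (SD, n = 8) in normal cells, 1.42 ± 0.10 (n = 3) in H1 and 1.64 ± 0.12 (n = 4) in H2. By exact two-sided permutation tests, none of 4 comparisons was past the threshold after adjustment, with p = 0.0222 (adjusted 0.0889) for H2 against normal and p = 0.0838 (adjusted 0.112) for all lesions against normal. For H1 against normal the exact p was 0.752, and for H1 against H2 it was 0.0571 (adjusted 0.112). The number of probe sets above a log2 signal of 6 ranged from 2553 in normal replicate 2 to 6292 in H2 replicate 7, with means of 3910 in normal cells, 3992 in H1 and 5126 in H2. The log2 difference between the 3′ and 5′ control probe sets, which varies with the state and amplification of the RNA, was also measured. For Actb it averaged -0.63 ± 0.62 (SD, n = 8) in normal cells, -0.70 ± 0.60 (n = 3) in H1 and -0.003 ± 0.23 (n = 4) in H2. For Gapdh it averaged 2.53 ± 0.59, 2.54 ± 0.35 and 3.32 ± 0.86 in the same order. H2 against normal had exact two-sided permutation p-values of 0.0546 (Actb) and 0.095 (Gapdh), with 0.253 for each adjusted over 8 comparisons.

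**Figure D1:**
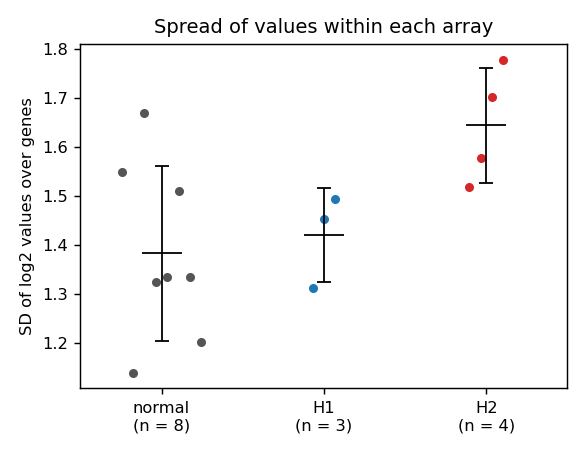
Standard deviation of the log2 gene values within each array (vertical axis, log2 units) for normal cells, H1 and H2, with 1 point per array and bars for the group mean ± SD. The H2 arrays lie between 1.52 and 1.78 and the normal arrays between 1.14 and 1.67.

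Lesions were compared with normal cells to ask which genes early K-Ras-driven growth changes. The imprinted long non-coding RNA Meg3 rose by 4.93 ± 0.47, or 30.5-fold, from 4.53 ± 0.66 (SD, n = 8) in normal cells to 9.46 ± 1.28 (SD, n = 7) in lesions (limma adjusted p = 0.000166). Mpzl2, an epithelial adhesion molecule, rose by 2.77 ± 0.31 to 6.10 ± 0.46 (adjusted p = 0.000879). Elastin (Eln), a protein of elastic fibres, rose by 2.83 ± 0.37 to 8.31 ± 0.75, and Piwil4, an Argonaute-family protein known from the germ line, rose by 3.18 ± 0.42 to 7.19 ± 1.06 (adjusted p = 0.00326 for each). Azin1, which raises polyamine synthesis, rose by 2.39 ± 0.33 (adjusted p = 0.00414). Of the ERK feedback genes, which active Ras signalling induces, Spred1 rose by 2.34 ± 0.41, Spry2 by 2.46 ± 0.45 and Phlda1 by 1.89 ± 0.33 (adjusted p = 0.0284 for each).

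Also higher were the lysosomal protease Ctsh (3.03 ± 0.51, adjusted p = 0.0255), the junction protein Marveld3 (2.56 ± 0.48, 0.0335), the ion transporter Slc12a2 (2.30 ± 0.44, 0.0345), the mucin Muc4 (2.02 ± 0.38, 0.0335), the transcriptional inhibitor Id2 (1.96 ± 0.33, 0.0254) and the kinase Nlk (1.92, 0.0497). The group values of the genes named here by size did not overlap. Meg3, Piwil4, Eln, Mpzl2 and Azin1 stayed past the threshold in each of 15 fits that left out 1 array. The other 7 did so in 4 (Nlk) to 11 (Id2) of them. Further genes were chosen after their values were seen. The histamine-forming enzyme Hdc rose by 3.45 ± 0.45 (adjusted p = 0.00326), the muscle myosin Myh7 by 3.72 ± 0.52 (0.00536) and the secreted protein Lcn2 by 1.86 ± 0.37 (0.0451). The 2 genes that fell were the integrin Itga8, at -2.46 ± 0.42 (0.0267), and Ankrd33b, at -1.58 ± 0.28 (0.0284). Where a group's mean lay below 3.99, the median of all probe set means, and so nearer to the background, the size of a change is not well determined. This was so in normal cells for Mpzl2 (3.32), Marveld3 (2.77), Phlda1 (3.96) and Lcn2 (3.73), and in lesions for Ankrd33b (3.19).

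A second probe set did not always show the change. Of 11 probe sets for Meg3, 9 moved the same way, but by unequal amounts. The largest shifts were 4.93, 3.39, 3.24 and 1.05, and the others lay between -0.27 and 0.67. The 30.5-fold rise is that of the highest probe set alone. The other probe set differed by -0.02 for Piwil4, by -0.02 for Eln, by 0.17 for Hdc and by 0.14 for Spry2. Of 3 probe sets for Marveld3, 1 was higher. Of 3 probe sets each, 2 were higher for Azin1 (the lowest at -0.19), Id2 (-0.06), Muc4 (-0.04) and Rrm2 (-0.11). Both probe sets for Ctsh (2.22 and 3.03) and all 3 for Slc12a2 (2.07 to 2.41) rose, and Myh7 had 1 probe set.

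**Figure D2:**
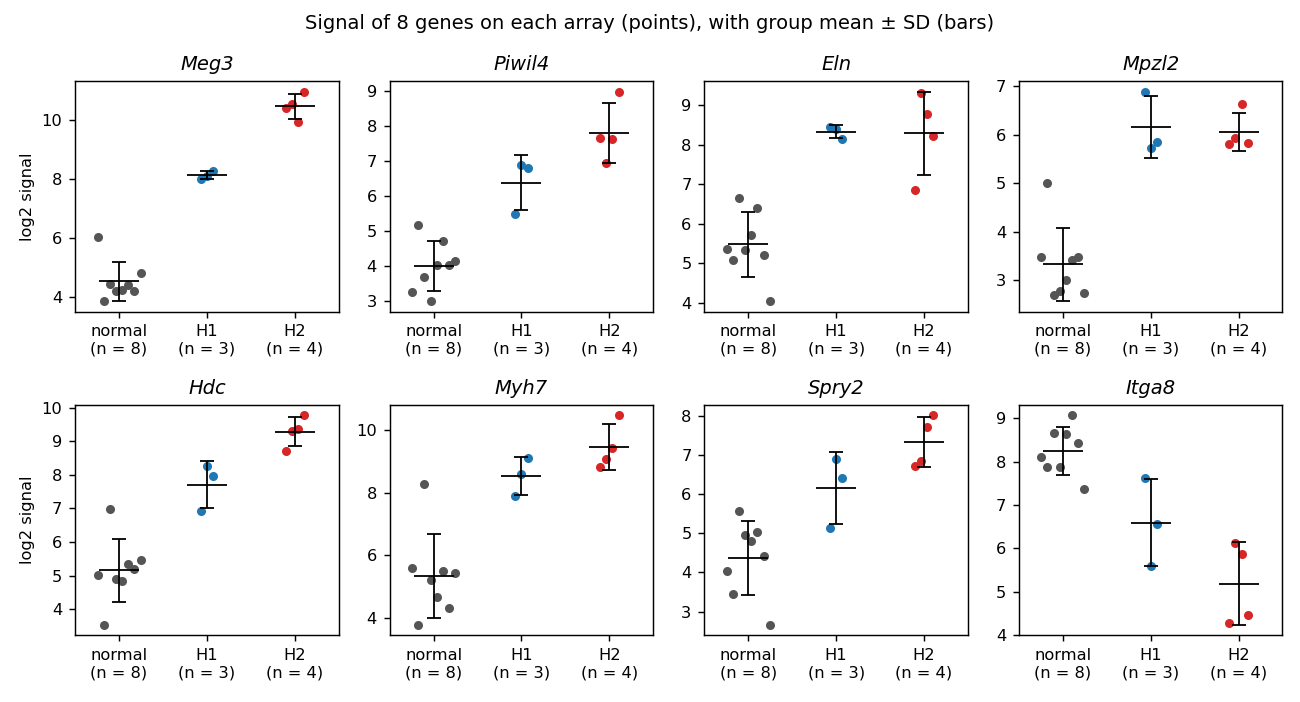
Log2 signal (vertical axis) of Meg3, Piwil4, Eln, Mpzl2, Hdc, Myh7, Spry2 and Itga8 on each array, by group, with 1 point per array and bars for the group mean ± SD. Meg3 averages 4.53 in normal cells, 8.13 in H1 and 10.45 in H2, and Itga8 averages 8.25, 6.59 and 5.19.

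Of the gene lists, the alveolar type 2 (AT2) cell and surfactant list shifted most. All 17 of its genes were higher, with a median of 1.23 (camera adjusted p = 2.82e-09; adjusted p = 0.317 with an estimated correlation). AT2 cells make surfactant, and Abca3, a surfactant lipid transporter, differed by 1.94 ± 0.46 (adjusted p = 0.08 over all genes), Lpcat1 by 1.99, Slc34a2 by 1.82 and Fabp5 by 1.82. None of the list was called by limma over all genes (11 at an unadjusted p under 0.05), and 10 were higher when adjusted over the list alone. The ERK output list had a median of 0.74 (adjusted p = 7.62e-06; adjusted p = 0.307 with an estimated correlation), with 3 genes called over all genes and 7 adjusted over the list alone. Endothelial genes, of the vessel lining, had a median of -0.57, with 18 of 20 lower (adjusted p = 0.000163; adjusted p = 0.376 with an estimated correlation). Ramp2 differed by -1.05, Calcrl by -1.53, Clec14a by -0.71 and Emcn by -0.77, and 0 were called by limma over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05).

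Epithelial junction and keratin genes had a median of 0.40 (adjusted p = 0.00217; adjusted p = 0.317 with an estimated correlation), with Cdh1 at 1.57, Krt8 at 2.04, Krt18 at 1.78 and Epcam at 2.19, and 5 genes higher adjusted over the list alone. Lipid and cholesterol synthesis genes had a median of 0.66 (adjusted p = 0.0071; adjusted p = 0.376 with an estimated correlation), with Scd1 at 2.48 ± 0.53, and 7 higher adjusted over the list alone. Targets of NRF2, the oxidative stress regulator, had a median of 0.37 (adjusted p = 0.00819; adjusted p = 0.317 with an estimated correlation), with 3 higher adjusted over the list alone, and Me1 at 1.81 and Gsta4 at 1.72. None of these 3 lists had a gene called by limma over all genes (5, 7 and 5 at an unadjusted p under 0.05). DNA replication genes had a median of 0.31 (adjusted p = 0.0423; adjusted p = 0.317 with an estimated correlation). Rrm2, which makes DNA building blocks, rose by 2.26 ± 0.43 (adjusted p = 0.0345), and 3 were higher adjusted over the list alone. MHC class I and interferon genes had a median of -0.32 (adjusted p = 0.0404; adjusted p = 0.451 with an estimated correlation). Ifit3 differed by -0.88, with 1 gene lower adjusted over the list alone and 0 called by limma over all genes (2 at an unadjusted p under 0.05). The other 23 of 31 lists did not pass camera. With array spread as a covariate, a choice made after the data were seen, the epithelial (median 0.11), lipid (-0.008), NRF2 (0.25) and DNA replication (0.10) lists did not pass (camera adjusted p from 0.0755 to 0.276). The other 4 lists passed in that fit, AT2 at 0.58, ERK output at 0.30, endothelial at -0.91 and MHC class I at -0.54. By fry, 1 list passed, ERK output (adjusted p = 0.0432). Medians and means differed in sign for 6 lists, none of which passed camera.

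In all, 51 genes were higher and 2 lower (limma, of 18193), with 1474 and 848 at an unadjusted p under 0.05. The balance changed with the processing, to 40 higher and 46 lower with the spread covariate and to 21 and 15 without the 2 normal arrays of narrowest spread. With 1 array left out, 8 to 229 were higher. The groups did not overlap for 41 genes, or 0.225%, where chance gives 0.0311%, and 17 of the 41 were called. Some of the captured regions may share an animal, so these p-values may be too small (sharing within a group) or too large (sharing between groups).

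H1 was compared with normal cells to ask what distinguishes the first lesion subtype. Meg3 rose by 3.60 ± 0.36, or 12.1-fold, to 8.13 ± 0.14 (SD, n = 3; limma adjusted p = 0.000503). Mpzl2 rose by 2.83 ± 0.42 to 6.16 ± 0.64 (n = 3; limma adjusted p = 0.043). Its mean of 3.32 in normal cells leaves the size of its change not well determined. Both changes lay outside the range of the normal arrays. Of 11 probe sets for Meg3, 7 were higher in H1 (the lowest at -0.52). With the mean of all probe sets Meg3 differed by 0.80 and with the replicate number as a block by 3.96, and it did not pass in either (adjusted p = 0.992 and 0.126). It passed in 11 of 13 other settings and in all 15 fits that left out 1 array. Mpzl2 passed in 10 of the 13. Mpzl2 stayed past the threshold in 2 of 15 fits that left out 1 array, those without normal replicate 2 or 3. Eln differed by 2.85 ± 0.50 (adjusted p = 0.222), Hdc by 2.55 ± 0.50 (0.351) and Myh7 by 3.19 ± 0.67 (0.475), none past the threshold.

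The AT2 list had a median of 1.23, with 16 of 17 genes higher (camera adjusted p = 1.47e-06; adjusted p = 0.498 with an estimated correlation). Endothelial genes had a median of -0.61 (adjusted p = 0.000518; adjusted p = 0.571 with an estimated correlation). Genes of ERK output had a median of 0.49 (adjusted p = 0.000518; adjusted p = 0.368 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone. Phlda1 differed by 1.54, Spred1 by 1.88 and Spry2 by 1.78 (adjusted p = 0.997 each over all genes). NRF2 targets had a median of 0.39 (adjusted p = 0.00397; adjusted p = 0.368 with an estimated correlation), lipid synthesis genes 0.16 and MHC class I and interferon genes -0.38 (adjusted p = 0.0344 for each; adjusted p = 0.571 with an estimated correlation for each). Of these 6 lists, limma called 0 genes over all genes. At an unadjusted p under 0.05, 2 AT2, 4 ERK, 1 NRF2 and 1 lipid gene were higher, and 2 endothelial, 2 MHC class I and 1 ERK gene were lower. In the lists other than ERK output, 0 were called by limma adjusted over the list alone. Of all genes, limma called 2 higher and 0 lower, with 336 and 434 at an unadjusted p under 0.05, and 254 genes did not overlap (1.40%, chance 1.21%). As regions may share an animal within or between groups, the p-values may be too small or too large.

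H2 was compared with normal cells for the second subtype. Meg3 rose by 5.93 ± 0.32, or 60.8-fold, to 10.45 ± 0.43 (SD, n = 4; limma adjusted p = 8.37e-08). Of its 11 probe sets, 10 were higher (the lowest at -0.34). Hdc rose by 4.13 ± 0.45 to 9.28 ± 0.44 (adjusted p = 0.000469), Myh7 by 4.12 ± 0.61 (0.00386) and Piwil4 by 3.79 ± 0.43 (0.000553; its other probe set differed by -0.13). Tc2n, a protein with C2 domains, rose by 3.64 ± 0.69 (adjusted p = 0.0127) and the metal-binding Mt1 by 3.63 ± 0.56 (0.00515; its other probe set differed by -0.29). Itga8 fell by 3.06 on the log2 scale, to 5.19 ± 0.95 from 8.25 ± 0.55 (adjusted p = 0.0028), as both of its probe sets did. Also lower were Gcap8 (-2.01 ± 0.44, adjusted p = 0.0225), the lipid transporter Abca8a (-1.96 ± 0.42, 0.0216), the retinol-storing enzyme Lrat (-1.77 ± 0.44, 0.0378), Myzap (-1.76 ± 0.32, 0.0116) and the oxidising enzyme Fmo1 (-1.75 ± 0.42, 0.0357). Sizes, and so the order by size, are not well determined where a mean lay below 3.99. That held in H2 for Gcap8 (2.41), Abca8a (3.09), Lrat (3.46), Myzap (3.70) and Fmo1 (3.30), and in normal cells for Mt1 (3.45) and Phlda1 (3.96).

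The ERK list had a median of 0.94 (camera adjusted p = 0.000152; adjusted p = 0.263 with an estimated correlation), with 6 genes called over all genes, and 10 higher and 1 lower adjusted over the list alone. Spry2 rose by 2.96 ± 0.49 (adjusted p = 0.00661), Spred1 by 2.69 (0.0098), Phlda1 by 2.14 (0.011) and Spred2 by 1.30 (0.0219; 3 of its 5 probe sets were higher, the lowest at -0.87). The other probe set of Spry2 differed by 0.12. Epithelial genes had a median of 0.83 (adjusted p = 0.000617; adjusted p = 0.263 with an estimated correlation), with 4 called over all genes and 7 adjusted over the list alone. Krt8 rose by 2.83 ± 0.48 (adjusted p = 0.00753), Cdh1 by 1.88 (0.02), Krt18 by 2.33 (0.0367) and Dsp by 1.41 (0.0373; 2 of 3 probe sets higher, the lowest at -0.15). All 17 AT2 genes were higher, with a median of 1.40 (adjusted p = 4.27e-06; adjusted p = 0.488 with an estimated correlation). Abca3 rose by 2.35 ± 0.52 (adjusted p = 0.0249), the 1 AT2 gene called over all genes, and 7 were called adjusted over the list alone. With array spread as a covariate the AT2 median in H2 was 0.209, with 13 genes higher and 4 lower, and the list did not pass (camera adjusted p = 0.542).

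Endothelial genes had a median of -0.64 (adjusted p = 0.00684; adjusted p = 0.558 with an estimated correlation), with 0 called by limma over all genes or over the list alone (1 higher and 7 lower at an unadjusted p under 0.05). Lipid synthesis genes had a median of 0.92 (adjusted p = 0.0336; adjusted p = 0.558 with an estimated correlation), with 4 higher and 1 lower over all genes, and 6 and 1 adjusted over the list alone. Elovl1 rose by 3.02 ± 0.73 (adjusted p = 0.0352), Acaca by 1.24 (0.0373; its other probe set differed by -0.08) and Scd1 by 2.56 (0.0398). Fads1 fell, at -0.97 ± 0.24 (0.0373), and its other probe set differed by 0.06. DNA replication genes had a median of 0.43 (adjusted p = 0.0416; adjusted p = 0.314 with an estimated correlation), with 3 called over all genes and 4 adjusted over the list alone. Mcm4 rose by 2.49 ± 0.46 (adjusted p = 0.0112), Rrm2 by 2.41 (0.0224) and Mcm6 by 2.69 (0.0364). Of 3 probe sets each, 2 were higher for Rrm2 (the lowest at -0.12) and Mcm6 (-0.62). Mitosis genes had a median of 0.38 (adjusted p = 0.0164; adjusted p = 0.366 with an estimated correlation), with Ccnb2, a mitotic cyclin, at 1.03 ± 0.25 (adjusted p = 0.0373), the 1 called over all genes, and 2 adjusted over the list alone. Both means of Ccnb2 were low, 2.52 in normal cells and 3.55 in H2, so that its size is not well determined. With the spread covariate the lipid (median -0.028), DNA replication (0.098) and mitosis (0.13) lists did not pass either, and the ERK, epithelial and endothelial lists passed. By fry, 5 lists passed, with ERK output and epithelial genes at an adjusted p of 0.00651 each.

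**Figure D3:**
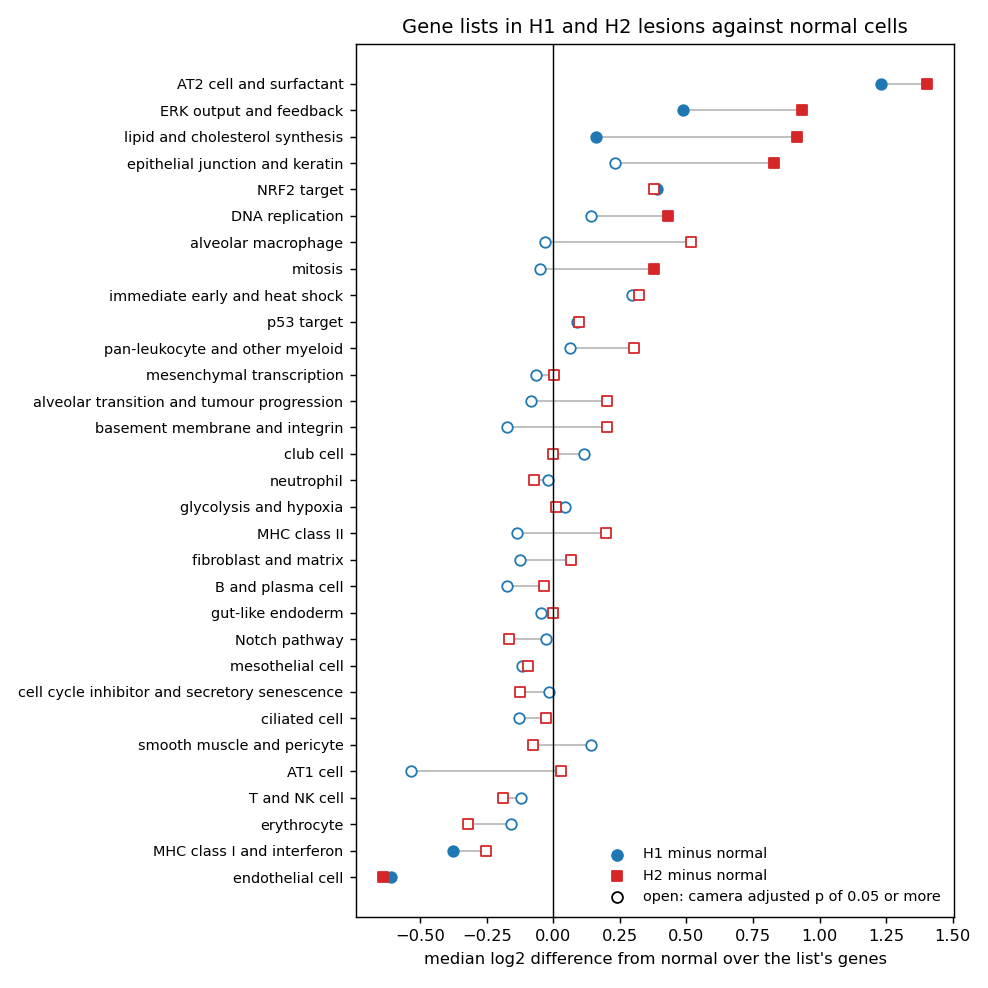
Median log2 difference from normal cells (horizontal axis) of each gene list in H1 (circles) and H2 (squares), filled where the camera adjusted p was under 0.05. The AT2 list lies at 1.23 in H1 and 1.40 in H2, and the endothelial list at -0.61 and -0.64.

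In H2, 525 genes were higher and 90 lower, with 2311 and 1582 at an unadjusted p under 0.05. The groups did not overlap for 689 genes (3.79%, chance 0.404%), and 387 of these were called. With array spread in the model, 57 were higher and 98 lower. The 3′ to 5′ ratios, added after the data were seen, gave 74 and 18 (Actb) and 39 and 10 (Gapdh) as covariates. As regions may share an animal within or between groups, the p-values may be too small or too large.

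H1 was compared with H2 to ask whether the subtypes differ. Muc4, a membrane mucin of epithelia, was lower in H1 by -2.01 ± 0.27, at 6.69 ± 0.25 (SD, n = 3) against 8.70 ± 0.31 (SD, n = 4; limma adjusted p = 0.0349). It was the 1 gene called. It stayed past the threshold in 4 of 13 other settings and in 6 of 15 fits that left out 1 array, and of its 3 probe sets 2 were lower. Meg3 differed by -2.33 ± 0.40 (adjusted p = 0.235), Krt8 by -1.85 ± 0.60 (0.319) and Ccnb2 by -1.24 ± 0.32 (0.28), none past the threshold.

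Epithelial junction and keratin genes were lower in H1, with a median of -0.88 (camera adjusted p = 0.0195; adjusted p = 0.636 with an estimated correlation), and mitosis genes had a median of -0.37 (0.0195; adjusted p = 0.636 with an estimated correlation). Limma called 0 genes of either list over all genes (6 epithelial and 3 mitosis genes lower at an unadjusted p under 0.05). Adjusted over the list alone, 3 epithelial genes and 1 mitosis gene were lower. Neither list passed with the replicate number as a block (medians of -0.65 and -0.59) or with array spread as a covariate (-0.31 and -0.15). Over all genes, limma called 0 higher and 1 lower, with 891 and 1349 at an unadjusted p under 0.05, and 3313 genes did not overlap (18.2%, chance 5.71%). If H1 and H2 were assigned from these profiles, this count is not independent evidence that the subtypes exist. Regions that share an animal could make its p-value too small (sharing within a subtype) or too large (sharing between them).

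Across genes, which are not independent replicates, the shifts of H1 and H2 from normal had a Pearson's r of 0.464. Unchanged groups that shared the normal arrays gave a mean of 0.300 in 100 simulations that drew each gene on its own. With the normal arrays split in 2 sets of 4, so that each shift had its own, r averaged 0.255 over 70 splits. It ranged from -0.301 to 0.575 with the choice of normal arrays. The splits reuse the same arrays, so this range is not a confidence interval for r. A relation beyond the shared arrays was not established.

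Ddr1, a collagen receptor chosen from knowledge of the study, did not pass the threshold in any comparison. It differed from normal by 1.22 ± 0.65 in lesions (adjusted p = 0.449), by 0.04 ± 0.74 in H1 (0.998) and by 2.11 ± 0.67 in H2 (0.0885). H1 minus H2 was -2.07 ± 0.83 (0.352). Its level was 5.91 ± 0.19 in H1, 7.98 ± 0.25 in H2 and 5.87 ± 1.59 in normal cells. The arrays of H1 (5.70 to 6.05) and H2 (7.62 to 8.18) did not overlap, as held for 18.2% of all genes. The SE of H1 minus H2 rests on a spread shared with the normal arrays, which varied far more. The fit thus does not settle whether the subtypes differ in Ddr1. The sign of its H1 difference changed with the processing, from -0.49 to 0.92. Of its 8 probe sets, 6 were higher in lesions, 1 in H1 and 6 in H2, and 6 were lower in H1 than in H2.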

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

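Of the tests below, array spread and the 3′ to 5′ ratios as covariates, and their random orders, were chosen only after the result was seen.

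H2 had 525 genes higher and 90 lower than normal cells. On average its arrays had wider value spreads and higher 3′ to 5′ ratios (differences of 0.63 for Actb and 0.79 for Gapdh), none of the 3 past the threshold after adjustment. As a covariate, array spread left 155 genes called in place of 615 (51 of them among the 615), the Actb ratio 92 and the Gapdh ratio 49. All 615 kept their direction in each of the 3 fits. Their median share of the shift was 0.673 with array spread, 0.840 with the Actb ratio and 0.827 with the Gapdh ratio, and the SE was a median of 1.11, 1.09 and 1.11 times as large. With the covariate's values in random order over the arrays, 10, 4 and 4 of 100 orders gave counts as low, and counts ran from 13 to 2722. All 3 counts fell below the bound set for a covariate as the cause, set before the test for the ratios only. A further condition, not part of that bound, was that most of the shift go with the covariate. It was not met for any of the 3, so the counts do not decide. Where the group means of a measure differ, such a fit may also remove part of a true difference. From the slopes on spread within the 8 normal arrays alone, the median predicted share of the shift of the called genes was 0.334 (0.292 to 0.422 without 1 normal array), between the bounds set beforehand. The slope was positive for 469 of the 525 higher genes and 21 of the 90 lower ones, against 53.9% of all genes. The directions of most called genes thus went with array spread among normal cells. Array spread and RNA state or amplification thus remain open as candidate explanations of part of the count, and were not separated from each other. A biological difference between lesion and normal cells stays open too. Meg3, Hdc, Myh7, Piwil4, Mt1, Mpzl2, Muc4 and Itga8 were past the threshold in H2 in every setting and leave-one-out fit run, and Ctsh in all but the fit with the Gapdh ratio.

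Splits of the same arrays into other groups were counted against the real ones. They exclude chance only if the samples are independent, which is not known, and do not allow for the 4 comparisons. For lesions against normal, 1 of 100 splits gave as many genes, the real one with 53, and the highest other gave 0, so chance can be excluded on that condition. For H2 against normal, 2 of 100 gave as many as 615, the real one among them. With the 4 comparisons not allowed for, that share is too large to exclude chance. With the replicate number as a block 39 were called. The highest other gave 1026, setting normal replicate 3 with H2 replicates 5, 6 and 7 against the rest, the 4 arrays of widest spread there, which points to a structure of the samples. For H1 against normal, 4 of 100 gave as many as 2. As the 4 comparisons are not allowed for, that share is too large to exclude chance, and Mpzl2, 1 of the 2 genes, passed in 2 of 15 leave-one-out fits. Also, normal replicates 1, 3 and 6 against the rest, the 3 arrays of widest spread there, gave 1727, again a structure of the samples. For H1 against H2, 2 of 35 gave as many as the 1 gene found, the highest other gave 3, and chance cannot be excluded.

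Single arrays lay far from the rest of their group for 4 of 48 groups of named-gene values, where chance picks out about 1 in 20, or 2.4. Meg3 was 6.03 in normal replicate 1 (others 3.86 to 4.81). Mpzl2 was 5.01 in normal replicate 2 (others 2.7 to 3.48) and 6.63 in H2 replicate 6 (others 5.8 to 5.94). Myh7 was 8.26 in normal replicate 3 (others 3.77 to 5.58).

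Differences between the subtypes that passed a test were Muc4 (H1 minus H2, -2.01), the epithelial list (median -0.88) and the mitosis list (median -0.37). Both lists lost the call with an estimated correlation (adjusted p = 0.636 each), with the replicate block (0.369 and 0.0508) and with the spread covariate (medians of -0.31 and -0.15, adjusted p = 0.127 and 0.085).

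Probe sets with no gene name or several, which no comparison used, also differed: of 10092, 10 were called in lesions (9 higher, 1 lower) and 128 in H2 (72 higher, 56 lower). These are 0.0991% and 1.27% of them, against 0.189% and 2.26% of the named probe sets.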

How the results depend on the processing

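Array spread or a 3′ to 5′ ratio as a covariate and the removal of normal replicates 2 and 8 were chosen only after the data were seen. Unless given, the cause of a change was not tested.

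Counts moved more than 1.5 times under these alternatives. With array weights, lesions against normal had 208 higher and 14 lower, H1 17 and 1, H2 1586 and 613, and H1 against H2 63 and 121. Repeated quantile normalization gave 10 lower in lesions, 140 higher and 46 lower in H2, and 0 lower in H1 against H2. The replicate number as a block gave 90 higher in lesions, 0 in H1, 34 higher and 5 lower in H2 and 0 lower in H1 against H2. Labels do not say that the numbers pair samples, and of 7 numbers 3 had a correlation over 0.1 between their lesion and normal arrays. With the spread covariate, 46 were lower in lesions, 15 higher and 6 lower in H1, 57 higher in H2 and 0 lower in H1 against H2. With the Actb ratio, 8 were lower in lesions, 74 higher and 18 lower in H2 and 0 lower in H1 against H2. With the Gapdh ratio, lesions had 20 higher and 1 lower, H2 39 and 10, and H1 against H2 0 lower. Without the narrow normal arrays, lesions had 21 higher and 15 lower, H2 293 and 54, and H1 against H2 2 lower. The mean of a gene's probe sets gave 0 higher in H1. For H1 against H2, that mean, the most variable probe set and the trended robust prior each gave 0 lower. With only the arrays compared, and so fewer samples, H1 had 1 higher, H2 39 lower and H1 against H2 0 lower.

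Leaving out 1 array at a time gave 8 to 229 higher and 0 to 9 lower genes in lesions, 1 to 5 higher in H1, 102 to 1104 higher and 16 to 274 lower in H2, and 0 to 2 lower in H1 against H2. The 51 higher genes in lesions became 130 without normal replicate 3 and 229 without H1 replicate 2. They became 11, 18, 15 and 12 without normal replicates 4, 5, 7 and 8, 21 and 27 without H1 replicates 3 and 4, and 24, 8, 11 and 13 without H2 replicates 1, 5, 6 and 7. The 525 in H2 became 821 and 1104 without normal replicates 1 and 3, 316, 313, 294 and 317 without normal replicates 4, 5, 7 and 8, and 284, 108 and 102 without H2 replicates 5, 6 and 7. The 90 lower in H2 became 193, 274 and 159 without normal replicates 1, 3 and 6, 43, 37, 31 and 46 without normal replicates 4, 5, 7 and 8, 53 without H1 replicate 3, and 48, 35, 16 and 17 without H2 replicates 1, 5, 6 and 7. H1 had 5 higher without normal replicate 3, 2 without normal replicate 2 or 4, and 1 without any other array.

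Some directions reversed. Ddr1 in H1 was -0.18 with the mean of probe sets, -0.20 with the most variable probe set, -0.18 with the spread covariate, -0.49 without the narrow normal arrays and -0.22 to 0.31 over the leave-one-out fits. Fads1 in H2 was 0.059 with the most variable probe set, and Cenpf in H1 against H2 was 0.015 with the mean of probe sets. With the spread covariate the lipid list had a median of -0.028 in H2 and -0.0084 in lesions (camera direction up).

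Of the other values of named genes, 3363 kept their direction and side of the threshold, 499 kept the direction and lost the threshold, and 70 gained it. For lists, with the direction taken from the test, the numbers were 409, 96 and 0. The spread covariate ended 10 list calls: epithelial, lipid, NRF2 and DNA replication in lesions, AT2 (median 0.209 from 1.40), lipid, DNA replication and mitosis in H2, and both between H1 and H2 (epithelial -0.31, adjusted p = 0.127; mitosis -0.15, 0.085). The replicate block ended 5 without shrinking all: DNA replication in lesions (0.36 from 0.31) and H2 (0.27 from 0.43), lipid in H1 (0.32 from 0.16), and between H1 and H2 epithelial (-0.65 from -0.88; 0.369) and mitosis (-0.59 from -0.37; 0.0508). Without dim genes 5 ended: DNA replication in lesions (0.38) and H2 (0.56), NRF2 in H1 (0.62), and mitosis in H2 (0.39) and between H1 and H2 (-0.36; 0.358). Without the narrow normal arrays 3 ended (DNA replication in lesions, lipid and NRF2 in H1), and with the mean of probe sets 1. With an estimated correlation, all 23 list results that had passed camera lost the threshold. With camera, 14 of the 23 passed in all 15 leave-one-out fits. In lesions the DNA replication and MHC class I lists passed in 9 each. In H1 the lipid list passed in 9 and MHC class I in 11. In H2, mitosis was lost without H2 replicate 7, lipid without H2 replicate 6 or 7, and DNA replication without normal replicate 3 or H2 replicate 7. Between H1 and H2, the epithelial list was lost without H1 replicate 2 or H2 replicate 5, and mitosis without H1 replicate 2 or 4 or H2 replicate 7. The correlation of the H1 and H2 shifts was 0.503 without dim genes and 0.309 to 0.594 with 1 array left out. No alternative moved the median of all genes by over 0.1. Signals near the background limit what can be seen of low transcripts.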

Other observations

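The macrophage against endothelial test below, the range over cell types and array spread as a covariate were chosen only after the results were seen, and the marker lists for heart muscle, mast cells and the Meg3 cluster were written after Myh7, Hdc and Meg3 were seen.

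Lists that did not pass camera in lesions were also measured. Macrophage genes, of the airspace scavenger cell, had a median of 0.30, and in H2 Fabp1 rose by 2.59 ± 0.57 (adjusted p = 0.0237; mean in normal cells 3.45). In the AT1 list, of the thin gas-exchange cell, the median was -0.21, with Rtkn2 at -1.51 ± 0.39 and Aqp5 at 1.47 ± 0.48 in lesions. Club cell genes, of the airway secretory cell, had a median of 0.00, yet in H2 Aldh1a7 rose by 2.26 ± 0.50 (0.0249) and Cyp2f2 by 1.57 ± 0.36 (0.0308; mean in normal cells 3.63). Of 11 club cell genes in H2, 5 were positive and 6 negative. Adjusted over the list alone, 2 were higher and 2 lower, Lypd2 at -0.79 ± 0.27 and Gabrp at -0.73 ± 0.28. Among fibroblast genes the median was -0.05 and the mean 0.17, with Col1a2 at 1.57 ± 0.37 (0.0341; 2 of 3 probe sets higher, the lowest at -0.28) in H2. T and NK cell genes had a median of -0.25, mesothelial genes -0.10 with Gpm6a at -1.66 ± 0.26 in H2 (0.0051), and Notch genes -0.09 with Notch2 at 1.77 ± 0.46 in H2 (0.0457; its other probe set differed by -0.06). The Notch2, Aldh1a7, Cyp2f2, Lypd2, Gabrp, Gpm6a and Fabp1 values were named after they were seen, and sizes against means below 3.99 are not well determined.

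Higher AT2 and lower endothelial genes in lesions could come from a larger share of AT2 cells with every other cell type lower alike. For signals well above the background, that would leave the macrophage minus endothelial score unchanged. That score was 0.985 higher in lesions (exact two-sided permutation p = 0.000622). It was the widest pair of the 9 cell types other than AT2 that were scored, and with that choice allowed for the exact permutation p was 0.0314. Both scores were below a log2 signal of 6, macrophage at 5.10 in lesions and 4.71 in normal cells, endothelial at 4.96 and 5.56. So near the background an equal fall need not lower both alike, and array spread was not allowed for. The test therefore cannot decide. By exact permutation tests adjusted over 10 cell types the single scores did not pass, with AT2 at 1.26 (p = 0.0148, adjusted 0.0746), club cell at 0.197 (p = 0.0149, adjusted 0.0746), endothelial at -0.595 (p = 0.0294, adjusted 0.0979) and macrophage at 0.39 (p = 0.101, adjusted 0.148). The AT2 call in lesions was lost with an estimated correlation (camera adjusted p = 0.317). With array spread as a covariate the AT2 median in lesions was 0.58, or 0.474 of its value of 1.23 without it (0.351 to 0.536 with 1 array left out; adjusted p = 0.00012), between the bounds set beforehand. In H1 the median was 0.929, or 0.755 of 1.23 (0.590 without normal replicate 3 to 1.00; adjusted p = 2.1e-08), and in H2 it was 0.209, or 0.149 of 1.40 (0.0259 to 0.349 without normal replicate 2), and the list did not pass (adjusted p = 0.542). H1 minus H2 reversed, from -0.53 without the covariate (camera adjusted p = 0.337; adjusted p = 0.953 with an estimated correlation) to 0.72 with it (camera adjusted p = 0.000682, at the preset correlation alone), so neither direction held in both fits. The values in H2 thus went with array spread as the cause and those in H1 against it as the whole cause, each with a range that crossed its bound (0.25 and 0.75), so that array spread stays open. A larger share of AT2 cells, alone or with other changes, and more AT2 transcript per cell were not separated by these tests.

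Meg3, Myh7 and Hdc could mark tissue other than the lesion. Heart muscle was argued against for Myh7, as 12 other heart muscle genes averaged -0.23 (95% interval -0.70 to 0.25), with Myh6 at 2.62 in lesions and 3.55 in normal cells and Tnnc1 at 5.13 and 5.69. Mast cells were argued against for Hdc, as 9 other mast cell genes averaged -0.18 (-0.35 to -0.0017), with Cpa3 at 3.03 and 3.01; of both sets 0 genes stood in another list and 0 averaged above a log2 signal of 6 in normal cells. For Meg3, 3 other genes of its imprinted cluster averaged 0.68 (-0.07 to 1.43), with Rian at 1.72 ± 0.62 (limma p adjusted over the set = 0.0403), Mirg at 0.37 ± 0.29 (0.34) and Dlk1, near the background, at -0.06 ± 0.17 (0.734). These values lie below the 4.93 of Meg3, but that is the highest of its 11 probe sets, which ran from -0.27. With 1 of the 3 genes higher over the set, the test could not decide by the bounds set before it. A shift of the whole cluster stays open. No biological explanation was tested beyond these.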
